A study of Mus musculus with 6 samples.

How the data were processed

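Sensory neurons of mouse dorsal root ganglia at embryonic stage E11.5 were dissociated with trypsin and collagenase, fixed with paraformaldehyde and sorted for the GFP of a Runx3 BAC reporter, as the labels describe. Each preparation used 50000 cells for ATAC-seq, for ChIP-seq with an H3K27ac antibody or for input DNA, with 2 replicates each. Libraries were amplified with at most 15 PCR cycles, kept fragments up to about 600 bp and were sequenced on a NextSeq 500. Per the labels, the authors used cutadapt 1.18, Bowtie2 2.3.5.1, MACS2 and bedtools, the last pair without a version, on the mm10 build. The deposited values are start and end positions in bp of 1 consensus list of peaks per assay, with no signal, score or p-value. How the authors formed the consensus, and with which thresholds, is not stated. Reads, counts and depth per sample are therefore unknown here, replicates cannot be compared, and the input DNA is not used here.

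Peaks were loaded with start positions counted from 0 and are printed counted from 1. Peaks on chromosomes 1 to 19, X and Y were analysed: 43652 of 43739 ATAC and 19924 of 19928 H3K27ac peaks, and none overlapped another of its own list. Genes were the 21883 protein-coding genes of the RefSeq annotation of GRCm38, the assembly of mm10. The annotation used gives gene spans without strand, transcripts or exons, and no genome sequence was used. The plan made before the data were examined named promoters, exons, introns and motifs. In their place, a gene end is the 1 kb on either side of either annotated end, other peaks are classed by their midpoint as inside or between genes, and motifs and CpG content were not analysed. RefSeq spans include predicted transcripts, so an annotated end can lie away from the start used in these cells; of 13219 genes with ATAC at an end, 1231 had it at both ends.

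Overlap means at least 1 shared bp. Overlap was tested against 1000 random rotations of the second set of intervals around each chromosome, from the lowest to the highest position of a peak or gene, because assembly gaps could not be removed. Position classes were compared by two-sided Fisher's exact tests, and widths by two-sided permutation tests of the mean log2 width with 100000 permutations. The 22 gene lists were written before the data were examined: 457 entries by symbol, all matched, 1 of them through a synonym, and 1465 olfactory and vomeronasal receptors by name pattern. Some genes stand in more than 1 list. Each list was compared with all other genes by two-sided Fisher's exact tests, adjusted by Benjamini-Hochberg over 44 tests. The proprioceptor list was compared directly with 2 other sensory lists, without shared members, over 4 tests. Genes, not animals, are the units of these tests. Odds ratios on the log2 scale have 0.5 added to each cell of the table; the odds ratio and interval of the direct comparison have nothing added.

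Distal ATAC peaks overlapping H3K27ac were assigned to the nearest gene end within 100 kb, and the mean per gene of each list was compared with 100000 random gene lists of the same size (list labels permuted over genes), two-sided, adjusted over 22 lists. H3K27ac peaks were stitched within 10 kb and ranked by covered bp, and lists were tested among the 12442 genes that have an end in a domain or nearest to it. For Runx3 and Ntrk3, peaks were counted from the neighbouring gene on one side to that on the other, and ranked among all genes. Tests passed at an adjusted p below 0.05. The genes named follow a rule set before the data were examined, except the members of gene lists named at the broadest domains, which were chosen after their values were seen. The rule names Runx3 and Ntrk3; from each list, up to 4 members with the most acetylated distal peaks and the exceptions where 5 or fewer members are with or without a peak; the genes at the 20 domains covering most bp; and the 20 genes with the most acetylated distal peaks. Not every gene that the rule takes is printed. The comparison of acetylation among open genes was added afterwards.

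Each result was recomputed with settings named before the data were examined: windows of 0.5 kb and 2.5 kb, the wider 50% of each list in place of a stricter threshold, 50% of the ATAC peak covered, autosomes only, rotation from position 1, assignment within 50 kb and 500 kb, random lists matched on the size of the nearest region, all distal ATAC peaks, stitching within 5 kb and 20 kb, single peaks in place of domains, and 50 kb around Runx3 and Ntrk3. Alternatives chosen after seeing the data were a peak anywhere in the gene, genes whose ends lie over 2 kb from other genes' ends, assignment of peaks inside a gene to that gene, and leaving out the peaks around Runx3. The procedures were also tested on simulated data: a list of 20 genes was called in 0% of 200 draws when its true acetylated share was 49.3%, in 12.5% at 75%, in 69.0% at 90% and in 69.5% at 10%. A list of 20 genes with 5-fold the mean of distal peaks passed an unadjusted test in 100% of 100 draws, and 1 without a difference in 3%. In the first simulation all other lists of the adjustment were random. Many real lists passed, which makes the real adjustment less strict. The distal counts were drawn from a Poisson distribution, and real counts spread more (SD 2.11 at a mean of 0.85 for proprioceptor genes). These rates are therefore not the power of the real tests. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.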

Results

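Open chromatin (assay for transposase-accessible chromatin with sequencing, ATAC-seq) and acetylation of lysine 27 of histone H3 (H3K27ac, a mark of active promoters and enhancers, by ChIP-seq) were mapped in mouse sensory neurons of the dorsal root ganglion at embryonic stage E11.5. The neurons carried GFP from a Runx3 bacterial artificial chromosome (BAC) and were sorted as TrkC neurons, the lineage of proprioceptors, which sense muscle stretch. The 6 samples form 3 groups of 2: ATAC, H3K27ac and input DNA. The values are 2 peak lists, each a consensus over the 2 replicates of its assay, with positions but no signal, so no spread between replicates can be given and the depth of each sample is unknown. The ATAC list held 43739 peaks with a median width of 217 bp, covering 12.2 Mb, and the H3K27ac list held 19928 peaks with a median width of 1036 bp, covering 25.5 Mb. Positions are on mm10 (GRCm38), counted from 1, and intervals of shares are 95% Wilson intervals that cover counting error only.

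The comparison of both lists asks where the open chromatin of these neurons also carried the active mark. Of 43652 ATAC peaks on the assembled chromosomes, 17280 (39.6%, 95% interval 39.1 to 40.0) overlapped an H3K27ac peak. Of 19924 H3K27ac peaks, 13728 (68.9%, 68.3 to 69.5) overlapped an ATAC peak. Random rotations of the H3K27ac peaks along each chromosome overlapped 554 ATAC peaks on average (SD 30.8 over 1000 rotations), so the observed overlap was 31.2-fold higher (two-sided circular permutation test, p = 0.002, the smallest these rotations can give).

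Gene ends were the most often acetylated open regions. Of 15108 ATAC peaks within 1 kb of an annotated end of a protein-coding gene, 11000 (72.8%, 72.1 to 73.5) overlapped H3K27ac. The share was 26.6% (25.9 to 27.3) of 15365 peaks inside genes and 16.6% (16.0 to 17.3) of 13179 peaks between genes. Against all other ATAC peaks, the log2 odds ratio of acetylation was 3.25 at gene ends, -1.27 inside genes and -2.30 between genes (two-sided Fisher's exact tests, 3 classes, each p below what the software can represent). Seen from the mark, 95.2% of the H3K27ac peaks at gene ends overlapped an ATAC peak, and 45.3% of those inside genes and 44.1% of those between genes did. With only the wider 50% of each list, the log2 odds ratio at gene ends was 1.70.

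Acetylated open regions were also wider. ATAC peaks with H3K27ac had a median width of 365 bp and those without had 165 bp, a difference of 0.95 in mean log2 width (SD 0.77 and 0.64 over 17280 and 26372 peaks). The difference was 0.70 at gene ends (medians 417 and 244 bp) and 0.72 at distal peaks, which lie over 1 kb from every gene end (medians 277 and 156 bp). Each of these 3 differences had a two-sided permutation p of 1e-05, the smallest that 100000 permutations can give.

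Most protein-coding genes with an acetylated end also had an open end. Of 21883 genes, 10451 had both an ATAC and an H3K27ac peak within 1 kb of an annotated end, 2768 had ATAC alone, 328 had H3K27ac alone and 8336 had neither. Thus 13219 genes (60.4%) were open and 10779 (49.3%) acetylated at an end. Of the open genes, 79.1% were acetylated, against 3.79% of the genes without an ATAC peak at either end. The log2 odds ratio was 6.58 (two-sided Fisher's exact test, p below what the software can represent). The annotation gives no strand, so either end of a gene counts, and the ATAC and H3K27ac peaks of a gene need not lie at the same end. Of all genes, 7045 share a window with the end of another gene. The number of genes with both marks was 6661 with the wider 50% of each list.

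Neuronal genes were among the most often open and acetylated gene groups. Of 24 pan-neuronal genes, 20 were open at an end (adjusted p = 0.0378) and 22 were acetylated (91.7%, interval 74.2 to 97.7; adjusted p = 0.000103, two-sided Fisher's exact tests against all other genes). Examples are Elavl4, which encodes a neuronal RNA-binding protein, Ncam1, a neural cell adhesion molecule, Celf4 and Rtn1. The members without acetylation at an end were Mapt, the gene of the microtubule protein tau, and Prph, that of the intermediate filament peripherin. Mapt held 8 ATAC and 2 H3K27ac peaks inside the gene, and Prph held neither. Of 26 pan-sensory transcription factors, 19 were acetylated (73.1%, interval 53.9 to 86.3; adjusted Fisher p = 0.0338) and 19 were open (adjusted p = 0.317), among them Ebf2, Klf7 and Pou4f2 with both marks. Ebf3 had no peak within 1 kb of an annotated end but 10 ATAC and 11 H3K27ac peaks inside the gene. Axon guidance and outgrowth genes were open in 23 of 28 cases (adjusted Fisher p = 0.0358), with Cntn2, Nrp2 and Sema6d as examples, and acetylated in 18 (adjusted p = 0.199). The members without an ATAC peak at an end were Chl1, Robo1, Robo3, Slit1 and Slit2. They held 2, 8, 2, 13 and 3 ATAC peaks inside the gene. The pan-neuronal ATAC call was lost with the wider 50% of each list, and the H3K27ac call of the pan-sensory factors with a window of 0.5 kb. With a window of 2.5 kb and with a peak anywhere in the gene, the ATAC share of the pan-sensory factors also passed, as did the H3K27ac share of the axon guidance genes with the latter.

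Among the markers of sensory subtypes, those of mechanoreceptors, the touch neurons, had the highest shares. Of 16 mechanoreceptor genes, 15 were open (adjusted Fisher p = 0.00987) and 13 acetylated (81.3%, interval 57.0 to 93.4; adjusted p = 0.0231). At an end, Cux2, Gfra1, Meis2 and Shox2 carried both marks, Th carried neither, and Mafa and Ret were open without H3K27ac. Th held 1 ATAC peak inside the gene. Of 20 proprioceptor genes, 12 were open (adjusted Fisher p = 1.0) and 7 acetylated (35.0%, interval 18.1 to 56.7; adjusted p = 0.347). Of 22 nociceptor and thermoreceptor genes, which serve pain and temperature sense, 10 were open (adjusted Fisher p = 0.270) and 6 acetylated (27.3%, interval 13.2 to 48.2; adjusted p = 0.0832). In the direct comparison, proprioceptor genes were acetylated less often than mechanoreceptor genes (odds ratio 0.133, 95% interval 0.0180 to 0.708; two-sided Fisher's exact test, p = 0.00791, adjusted p = 0.0316 over 4 tests). The ATAC difference between these lists did not pass (60.0% against 93.8%, adjusted Fisher p = 0.0521), nor did the differences from the nociceptor list (adjusted p = 0.499 for ATAC and 0.741 for H3K27ac).

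Several proprioceptor genes carried H3K27ac outside the 1 kb windows at their annotated ends. Runx3, Ntrk3 (which encodes TrkC), Esrrg and Ntng1 had no H3K27ac peak within 1 kb of an annotated end, but held 3, 4, 4 and 2 H3K27ac peaks inside the gene. The widest at Ntrk3, 3949 bp with 3 ATAC peaks inside it, stopped 1250 bp from the annotated end, just outside the window. The direct difference did not pass when a peak anywhere in the gene counted (log2 odds ratio -1.10, adjusted Fisher p = 0.492). It passed with a window of 2.5 kb (adjusted Fisher p = 0.0229), but not with 0.5 kb (adjusted p = 0.184), with the wider 50% of each list (adjusted p = 0.0558) or with genes whose ends lie apart from those of other genes (adjusted p = 0.0994). The mechanoreceptor H3K27ac call itself was lost with 0.5 kb, with the wider 50% and with a peak anywhere in the gene, and its ATAC call with the wider 50%; the nociceptor list fell below other genes for H3K27ac with 0.5 kb and with 2.5 kb.

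Immediate early, cell cycle and housekeeping genes were open and acetylated more often than other genes. All 20 immediate early and dissociation response genes, which respond to stimulation and tissue handling, were open (adjusted Fisher p = 0.00036). Of these, 19 were acetylated at an end (adjusted Fisher p = 0.000103), with Ier2, Fos, Atf3 and Btg2 as examples. The exception, Egr2, held 1 H3K27ac peak inside the gene. Of 24 cell cycle genes, 23 were open at an end (adjusted Fisher p = 0.000735, all but Cdkn1a). At an end, 20 were acetylated (83.3%, adjusted Fisher p = 0.00229, without Bub1, Ccnd1, Cdkn1a and Mcm3). Cdkn1a held 2 ATAC peaks and 1 H3K27ac peak inside the gene, and Bub1, Ccnd1 and Mcm3 held no H3K27ac peak there. Of 23 housekeeping genes, 20 were open at an end (adjusted Fisher p = 0.0193, without Actb, Reep5 and Ywhaz). At an end, 21 were acetylated (91.3%, adjusted Fisher p = 0.000156, without Reep5 and Ywhaz). Actb, Reep5 and Ywhaz held 2, 1 and 3 ATAC peaks inside the gene, and Reep5 and Ywhaz held 1 H3K27ac peak each there. Hox genes, which specify position along the body axis, were acetylated in 29 of 39 cases (74.4%, adjusted Fisher p = 0.0049). They were open at an end in 23 (adjusted Fisher p = 0.935). Neighbouring Hox genes share wide H3K27ac peaks and are not independent, which the Fisher test ignores. The cell cycle H3K27ac call was lost with the wider 50% of each list, and the housekeeping ATAC call with genes whose ends lie apart.

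3 other lists of neuronal or signalling genes did not pass for either mark. Neurotrophin signalling genes were open at an end in 18 of 22 cases (adjusted Fisher p = 0.0788) and acetylated in 16 (adjusted p = 0.0548). The members not open there, Bcl2l1, Bdnf, Ntf3 and Ntrk3, held 6, 5, 1 and 7 ATAC peaks inside the gene. Potassium, sodium and calcium channel genes were open in 16 of 23 cases (adjusted Fisher p = 0.493) and acetylated in 12 (adjusted p = 0.920). Glutamatergic transmission genes were open at an end in 10 of 13 cases (adjusted Fisher p = 0.347). The others, Gria2, Gria3 and Grik2, held 1, 0 and 2 ATAC peaks inside the gene. Glutamatergic genes were acetylated in 5 cases (adjusted Fisher p = 0.673): Gria2, Gria4, Grik1, Slc17a6, which encodes a vesicular glutamate transporter, and Slc1a2. The neurotrophin list passed for H3K27ac at 2.5 kb, with the wider 50% of each list and with a peak anywhere in the gene. For ATAC it passed with 0.5 kb and anywhere in the gene. The channel list passed for both marks with a peak anywhere in the gene. Longer genes leave more room for such a peak, and this setting was not matched on gene length.

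Of 9 lists of genes of other cell types or tissues, 8 were acetylated less often than other genes. The exception was the list of satellite glia, Schwann cell precursors and neural crest, with 11 of 22 genes acetylated (50%, interval 30.7 to 69.3; adjusted Fisher p = 1.0) and 15 open (adjusted p = 0.618). None of 17 endothelial and mural genes was acetylated (upper limit 18.4%; adjusted Fisher p = 0.000103). Of 19 dorsal spinal interneuron genes, 1 was (Foxd3; adjusted Fisher p = 0.00036), and of 19 motor neuron and ventral spinal cord genes, 3 were (Foxp1, Nkx6-1 and Slc5a7; adjusted p = 0.00987). Of 22 skeletal muscle and sclerotome genes, 3 were acetylated (Foxc1, Tcf15 and Twist1; adjusted Fisher p = 0.0024). The counts were 2 of 21 blood and immune genes (Cd4 and Klf1; adjusted Fisher p = 0.000831) and 2 of 20 genes of liver, gut and skin epithelium (Apoa2 and Lor; adjusted p = 0.00129). They were 1 of 17 germ cell and pluripotency genes (Dazl; adjusted Fisher p = 0.000947) and 2 of 1465 olfactory and vomeronasal receptor genes (Olfr558 and Vmn1r4). In all, 7 of 22 lists were acetylated more often than other genes and 8 less often. The motor neuron call was lost with genes whose ends lie apart, and the epithelium call with the wider 50% of each list.

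**Figure D1:**
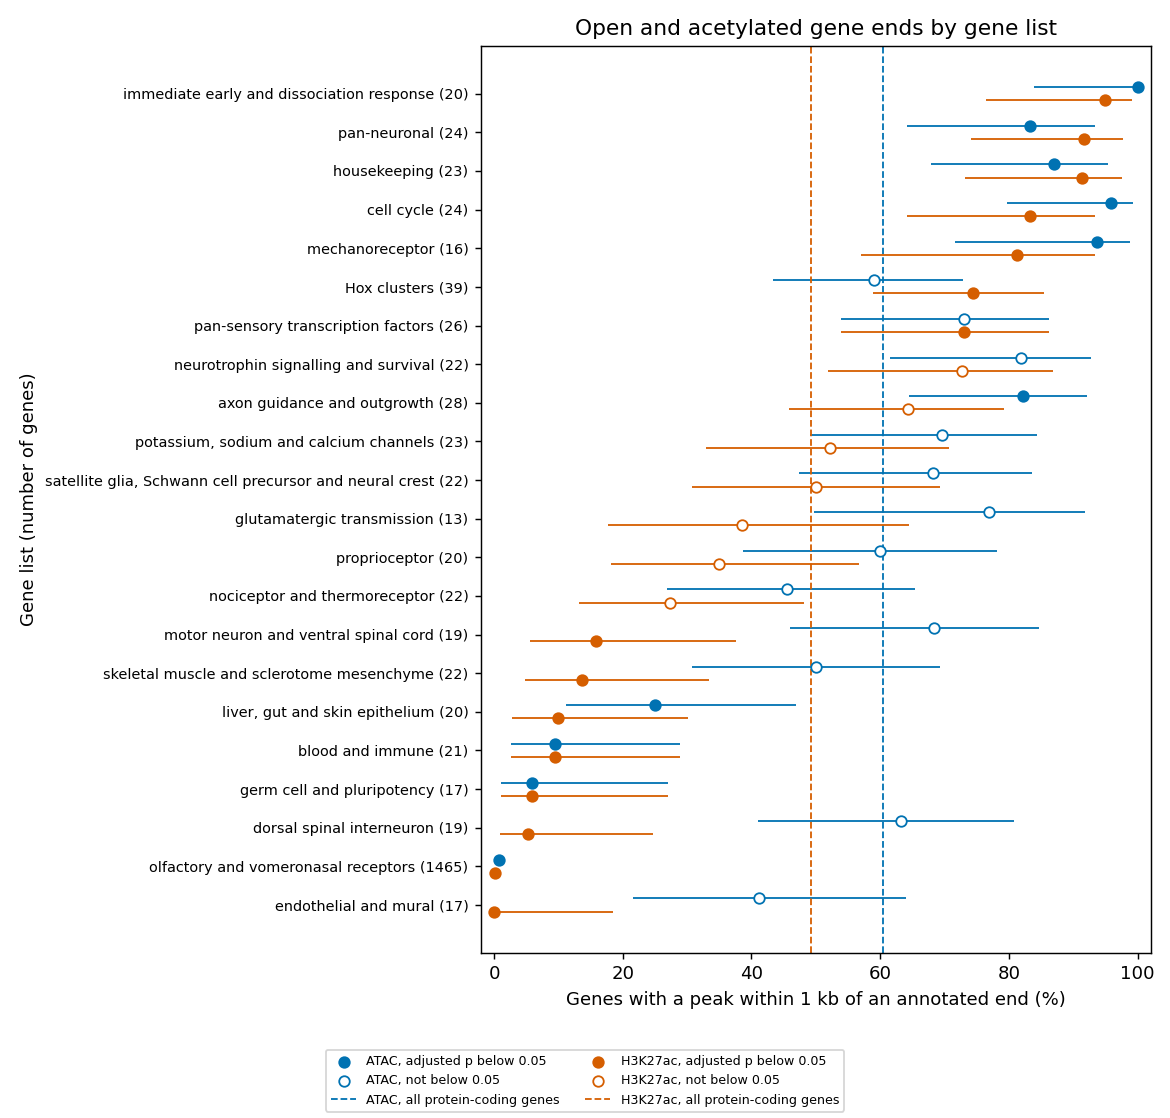
Share of the genes of each list with an ATAC peak (blue) or an H3K27ac peak (orange) within 1 kb of an annotated end, in percent, with 95% Wilson intervals as bars. Filled points passed Fisher's exact test against all other genes after adjustment over 44 tests, and the dashed lines give the shares over all 21883 genes (60.4% and 49.3%).

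Markers of 4 of these cell types were also open less often than other genes. The ATAC share was below that of other genes for blood and immune genes (2 of 21: Cd4 and Spi1; adjusted Fisher p = 2.69e-05), germ cell and pluripotency genes (1 of 17: Dazl; adjusted Fisher p = 4.24e-05) and epithelium genes (5 of 20: Apoa1, Apoa2, Cdx2, Epcam and Lor; adjusted Fisher p = 0.0049). Of the olfactory and vomeronasal receptors, 11 of 1465 were open (p below what the software can represent). The ATAC share of other spinal, mesenchymal and vascular markers did not pass: 13 of 19 motor neuron genes (adjusted Fisher p = 0.722), 12 of 19 dorsal interneuron genes (adjusted p = 1.0), 11 of 22 mesenchyme genes (adjusted p = 0.483) and 7 of 17 endothelial genes (adjusted p = 0.199) were open. With a window of 2.5 kb, the motor neuron and dorsal interneuron lists were open more often than other genes, the former also with a peak anywhere in the gene. The endothelial list was open less often with a window of 0.5 kb, and the epithelium ATAC call was lost with genes whose ends lie apart.

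Many of these open genes lacked acetylation, in a comparison added after the data were examined. None of the 12 open dorsal interneuron genes was acetylated, against 79.1% of other open genes (adjusted p = 1.53e-07, two-sided Fisher's exact tests over 22 lists); Atoh1 and Lmx1a are examples. The counts were 0 of 7 open endothelial genes (adjusted Fisher p = 0.000129; Sox17 is an example), 3 of 11 mesenchyme genes (adjusted p = 0.00144; Col1a1 and Col1a2 lacked the mark) and 3 of 13 motor neuron genes (adjusted p = 0.000134). They were 4 of 10 nociceptor genes and 4 of 10 glutamatergic genes (adjusted Fisher p = 0.0253 for each), and 1 of 11 olfactory and vomeronasal receptors (adjusted p = 1.57e-05). All 20 open pan-neuronal and all 20 open housekeeping genes were acetylated (adjusted Fisher p = 0.0312 for each). The calls for the dorsal interneuron, endothelial and mesenchyme lists passed under all 5 alternatives, whereas with the wider 50% of each list only these 3 lists fell below other open genes. The pan-neuronal and housekeeping calls were lost with a window of 0.5 kb, with the wider 50% and with genes whose ends lie apart, the glutamatergic call under all alternatives but 0.5 kb, and the nociceptor call also with a peak anywhere in the gene.

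Distal open regions with H3K27ac gathered near neuronal and sensory genes. Of 28544 distal ATAC peaks, 6280 (22.0%) overlapped H3K27ac, and 5445 of these lay within 100 kb of a gene end and were assigned to the nearest one, a mean of 0.249 per gene. Pan-neuronal genes had 2.33 (SD 2.46 over 24 genes), 9.37-fold the mean of random gene lists (adjusted permutation p = 0.00015); Elavl4 had 9, Celf4 7, Ncam1 6 and Rtn1 5. Pan-sensory transcription factors had 1.77 (SD 1.95 over 26 genes), 7.12-fold the random mean (adjusted permutation p = 0.00015); Ebf2 had 7, Ebf3 and Klf7 5 each, and Pou4f2 4. For both lists the raw p was 2e-05, the smallest that 100000 random lists can give, two-sided.

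8 further lists lay above random lists. Immediate early genes had a mean of 1.35 per gene (adjusted permutation p = 0.00033; Ier2 4, Fos 3), axon guidance genes 0.964 (adjusted p = 0.0037; Sema6d 4) and mechanoreceptor genes 0.938 (adjusted p = 0.031; Cux2 4, Gfra1 and Shox2 3 each, Meis2 2). Glial and neural crest genes had 0.909 (adjusted permutation p = 0.019; Gfra3 4, Tfap2a and Zeb2 3 each), proprioceptor genes 0.85 (adjusted p = 0.031; Runx3 9, Ntrk3 3, Esrrg and Ntng1 2 each) and neurotrophin signalling genes 0.773 (adjusted p = 0.038; Bcl2l1 4, Bdnf 3). Channel genes had 0.739 (adjusted permutation p = 0.041; Scn3a 4, Cacna1a 3) and Hox genes 0.667 (adjusted p = 0.029; Hoxc4 5, Hoxd3 4). The 3 peaks counted at Ntrk3 all lay inside 1 H3K27ac peak that stopped 1250 bp from the annotated end. Distal counts can thus include regions just outside the 1 kb window. Olfactory and vomeronasal receptors had 0.00819 (adjusted permutation p = 0.00015), the 1 list below random lists. Slc17a6 had 5 in the glutamatergic list, which did not pass (mean 0.846, adjusted permutation p = 0.068), and Gfra3 and Prdm12 had 4 and 2 in the nociceptor list (mean 0.455, adjusted p = 0.33). The other lists that did not pass were housekeeping (mean 0.565, adjusted permutation p = 0.15), cell cycle (0.292, adjusted p = 0.79), dorsal interneuron (0.158, adjusted p = 0.82), blood (0.143, adjusted p = 0.76) and endothelial (0.118, adjusted p = 0.75). So were germ cell (0.0588, adjusted permutation p = 0.43), motor neuron (0.0526, adjusted p = 0.35), epithelium (0.050, adjusted p = 0.33) and mesenchyme (0 in 22 genes, adjusted p = 0.086).

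Matching random lists on the size of the region nearest to each gene left 4 of the 10 lists above random lists: pan-neuronal, pan-sensory, immediate early and Hox; housekeeping genes then also lay above and mesenchyme genes below. The mechanoreceptor call was also lost within 50 kb, the mechanoreceptor, neurotrophin and Hox calls within 500 kb and with peaks inside a gene assigned to that gene, and the immediate early and Hox calls with all distal ATAC peaks. The proprioceptor call rested on 1 gene, since without the peaks around Runx3 its adjusted p was 0.466 (0.0505 to 0.225 under the other alternatives with H3K27ac). Across all genes, those with the most acetylated distal peaks included Gins2 and Maml3 (13 each), Cxxc5 (12), Cstad (11), and Bcor, which encodes a transcriptional corepressor, Nol4l and Zfp608 (10 each). Elavl4 and Runx3 followed with 9 each. Bach2, Bahcc1, Fancc, Phc2, Rbfox2, Septin9 and Zfp516 had 8 each, and 1700001O22Rik, Celf4 and Chd7 7 each. Peaks go to the nearest end even when they lie inside another gene. A stitched H3K27ac domain nearest to Gins2 overlapped Gse1, and 1 nearest to Fancc overlapped Aopep.

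The broadest acetylated regions covered the Hox clusters. Stitching H3K27ac peaks within 10 kb gave 16290 domains, of which 424 covered more than 5214 bp, the point where the ranked curve of covered length reaches slope 1. These 424 held 14.6% of all acetylated bp. The broadest was a single peak of 85.8 kb over Hoxb2 to Hoxb9 (chromosome 11, 96269602 to 96355399). Others among the 4 broadest were domains with 56.6 kb covered over Hoxc4 to Hoxc11 (chromosome 15, 102954931 to 103042526) and 35.2 kb over Hoxd1 to Hoxd11 (chromosome 2, 74682771 to 74763597). Because length stands in for signal, these domains are not ranked by the strength of the mark.

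**Figure D2:**
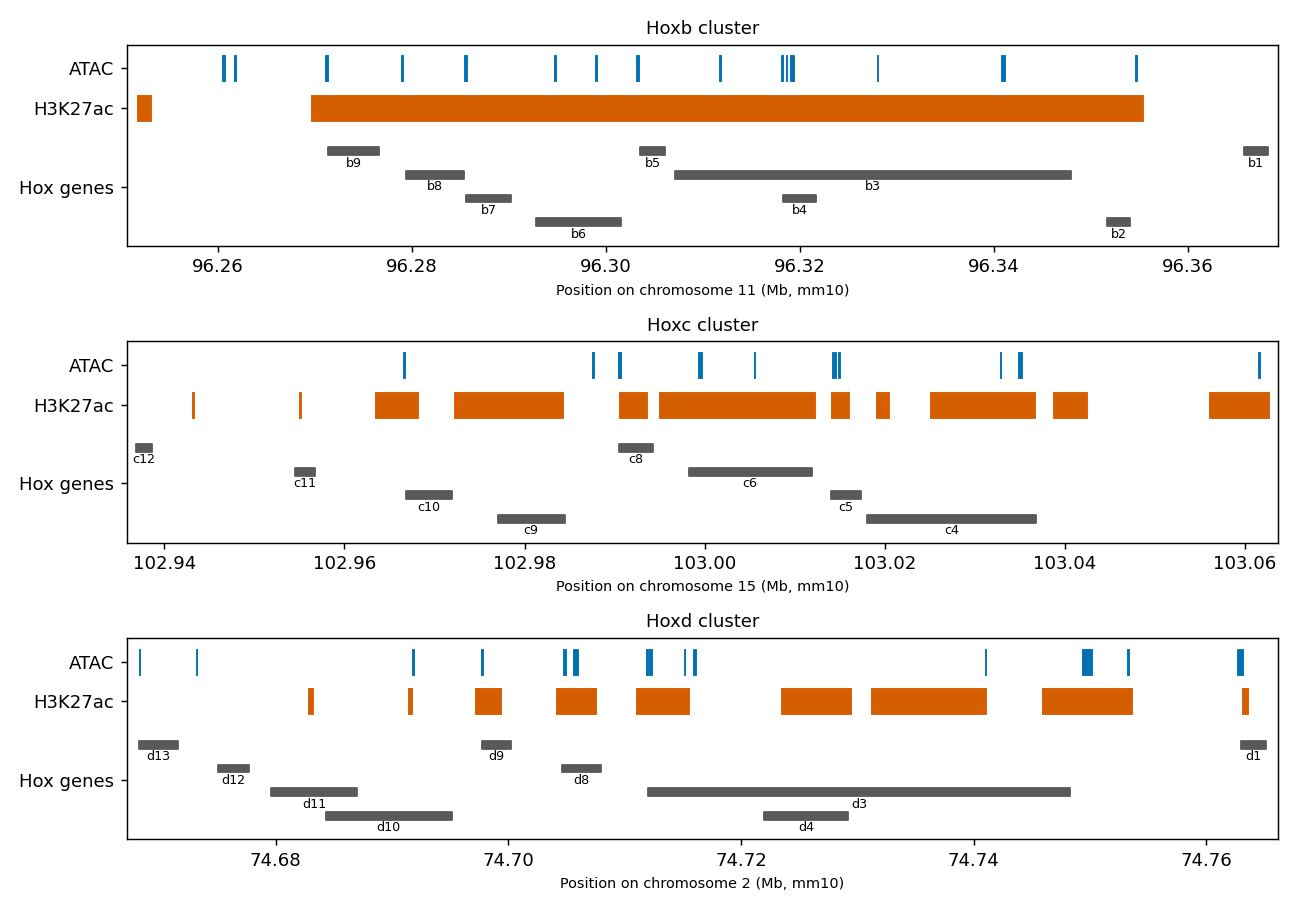
Maps of the Hoxb, Hoxc and Hoxd clusters with ATAC peaks (blue), H3K27ac peaks (orange) and Hox genes (grey), against position in Mb on mm10. A single H3K27ac peak of 85.8 kb spans Hoxb2 to Hoxb9; thin peaks are drawn with the width of their outline and look slightly wider than to scale.

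Broad domains also lay at or nearest to sensory and neuronal genes. A gene counts at a domain if it has an end in it or is the nearest gene. Gfra3, for example, had no H3K27ac peak within 1 kb of an end or inside the gene. Tlx3 stands in both the pan-sensory and the nociceptor list. Unlike the distal test, these tests were not matched on region size. Of 24 pan-sensory transcription factors with a domain, 13 lay at one of the 424 broadest, against 4.97% of other genes (log2 odds ratio 4.49, adjusted p = 2.09e-10, two-sided Fisher's exact test). Among them were Ebf1, Ebf3, Eya2, Hmx1, Isl1, Isl2, Klf7, Neurod1, Pou4f1, Prrxl1, Tlx2 and Tlx3, chosen for naming after their values were seen. Isl1, needed for sensory neuron identity, was covered by a single peak of 18.8 kb (chromosome 13, 116296500 to 116315293), and Nefm, which encodes a neurofilament, was the gene nearest to 19.6 kb on chromosome 14. Of 23 pan-neuronal genes, 7 lay at such domains (adjusted Fisher p = 0.000728), as did 31 of 33 Hox genes (adjusted p = 3.56e-37; neighbours share domains and are not independent). The counts were 4 of 11 for nociceptor genes (Gfra3, P2rx3, Prdm12 and Tlx3; adjusted Fisher p = 0.00888) and 5 of 26 for axon guidance genes (Cntn2, Nrp1, Nrp2, Robo1 and Sema6d; adjusted p = 0.0391), also named after their values were seen.

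Other lists did not pass: mechanoreceptor (3 of 14: Gfra1, Meis2 and Shox2) and housekeeping (4 of 23) at an adjusted p of 0.0973 each, glia and neural crest (3 of 17, adjusted Fisher p = 0.142), and proprioceptor (1 of 12, Runx3; adjusted p = 0.851). Nor did immediate early (3 of 18, adjusted Fisher p = 0.146), neurotrophin signalling (2 of 19, adjusted p = 0.550) and glutamatergic genes (1 of 8, adjusted p = 0.680), and the other 10 lists had no member at these domains. Others of the 20 broadest domains lay at or nearest to Cstad, Gins2 (inside Gse1), Zmynd8, Tspan18, Bahcc1, Nr2f2, Fancc (inside Aopep), Skida1 and Mllt10, Basp1, Phc2, Nefm, Tshz1 and Zadh2, Epb41, Synpo and Isl1. They covered 31.6 kb at Cstad to 18.8 kb at Isl1. The nociceptor call was lost with stitching within 20 kb and with single peaks, the pan-neuronal call with 20 kb, and the axon guidance call with 5 kb and 20 kb. The mechanoreceptor list passed with 5 kb and with single peaks, and the immediate early and housekeeping lists with 20 kb.

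The Runx3 and Ntrk3 loci were examined because the reporter is a Runx3 BAC and the cells are TrkC neurons. Runx3, a transcription factor gene (chromosome 4, 135120645 to 135177990), lies in an interval of 276 kb between Syf2 and Clic4 that held 53 ATAC peaks, the second highest number around any of 21883 genes. That is 19.2 peaks per 100 kb, against 1.62 over the genome. Of these peaks, 39 lay on the Syf2 side, 13 inside the gene and 1 on the Clic4 side, and 13 overlapped H3K27ac. The 9 H3K27ac peaks of the interval ranked 270. The transgene adds copies of part of this region, whose extent is not given, and input DNA was not analysed here.

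Ntrk3 (chromosome 7, 78179986 to 78581034) lies in an interval of 1651 kb with 15 ATAC peaks (rank 386), 8 H3K27ac peaks (rank 354) and 3 ATAC peaks overlapping H3K27ac. Its ATAC density of 0.909 per 100 kb was below the 1.62 of the genome. The number of peaks within 50 kb of each gene gave ranks of 61 (ATAC) and 3207 (H3K27ac) for Runx3, and of 1453 and 567 for Ntrk3. These ranks carry no test.

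**Figure D3:**
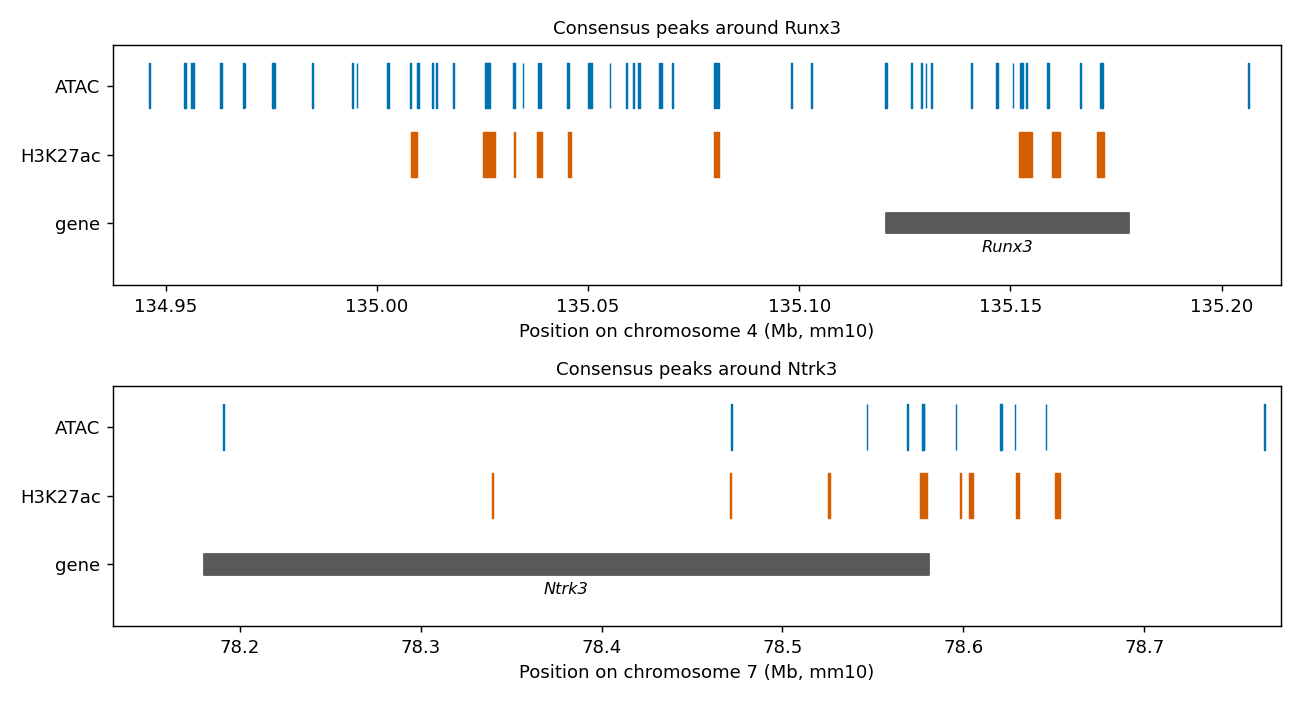
Maps of the Runx3 and Ntrk3 loci with ATAC peaks (blue), H3K27ac peaks (orange) and genes (grey), against position on mm10. Of 53 ATAC peaks around Runx3, 39 lie on the Syf2 side; the Ntrk3 map begins 50 kb left of the gene and so leaves out ATAC peaks further left, and thin peaks look slightly wider than to scale.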

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

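On contigs that are not placed on a chromosome, which the comparisons leave out, the ATAC list held 87 peaks and the H3K27ac list held 4. Each lies above the 3 that a count of 0 allows. No number of peaks was predicted for these contigs, so neither count is called an excess. Of the 87 ATAC peaks, 22 lay on a single contig and 5 overlapped H3K27ac.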

How the results depend on the processing

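No paired analysis was possible because each list pools its replicates, so leaving out a replicate could not be run either; depth is unknown and its effect could not be examined. Settings named beforehand that needed strand, transcripts or sequence (5′ ends only, CpG strata, motif windows and backgrounds) were not run. A peak anywhere in the gene, genes with ends apart, assignment by gene and leaving out the Runx3 peaks were chosen after seeing the data, as were all alternatives for acetylation among open genes. Of the main values and counts, 74 kept their direction and side of the threshold or stayed within their range, 14 moved and 4 lost their call; of single lists, 409 kept both, 48 lost a call, 27 gained one and 44 changed sign. Causes were not tested, except where fewer peaks or genes enter by construction.

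Genes with both marks numbered 6661 with the wider 50% of each list (fewer peaks) and 5649 with ends apart (fewer genes), from 10451. With a peak anywhere in the gene, which was not matched on gene length, 10 lists were open above other genes, 6 of them shared with the 6 found otherwise. The proprioceptor against mechanoreceptor log2 odds ratio for H3K27ac, -2.80, was -1.91 at 0.5 kb (adjusted Fisher p = 0.184), -2.66 with the wider 50% (0.0558), -1.10 anywhere in the gene (0.492), -2.64 with ends apart (0.0994) and -3.09 at 2.5 kb (0.0229).

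Log2 odds ratios of these lists changed sign, none past the threshold either way. ATAC at 0.5 kb: channels -0.015, glia -0.13, motor neuron -0.23. ATAC at 2.5 kb: proprioceptor 0.52, Hox 0.92. ATAC with the wider 50%: glia -0.25, motor neuron -0.99, dorsal interneuron -0.39. ATAC anywhere in the gene: proprioceptor 1.66, mesenchyme 0.12, Hox 0.26. ATAC with ends apart: proprioceptor 0.36, mesenchyme 0.057, endothelial 0.13, Hox 0.58. H3K27ac: channels -0.20 and glia -0.089 at 0.5 kb, channels -0.37 with the wider 50%, proprioceptor 0.53 anywhere in the gene, glutamatergic 0.38 with ends apart.

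Among open genes, 0 lists (from 2) were acetylated above others at 0.5 kb and 0 with ends apart, and 3 (from 7, all 3 shared) lay below with the wider 50%. Signs changed, none past the threshold, for mechanoreceptor -0.76 and neurotrophin -0.29 at 0.5 kb, channels 0.17 at 2.5 kb, mechanoreceptor -0.14 and axon guidance 0.16 with the wider 50%, axon guidance 1.02 and channels 2.00 anywhere in the gene, and channels 0.68 and germ cell 0.060 with ends apart.

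For distal peaks, 5 lists lay above (4 of the 10 shared) and 2 below (from 1) with lists matched on region size, and 6 above (all shared) both within 500 kb and with assignment by gene. The difference from the random mean, in peaks per gene, changed sign for blood within 500 kb (0.143). With all ATAC peaks it did so for motor neuron (1.36, adjusted permutation p = 0.0278), dorsal interneuron (2.10, adjusted p = 0.00192), mesenchyme 0.568, endothelial 1.06, Hox -0.139, whose call was lost, and housekeeping -0.200.

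For domains, lists with 0 members at the broadest domains, whose sign comes from the 0.5 added, changed sign with 20 kb stitching: channels 0.81, motor neuron -0.33, dorsal interneuron -0.036, mesenchyme -0.57, endothelial -0.036, cell cycle 0.098; and with single peaks: channels 0.015, olfactory 0.33. Within 50 kb of the gene, the percentiles among genes were 99.6 for Runx3 ATAC (from 99.98), 75.6 for Runx3 H3K27ac (from 98.4), 90.8 for Ntrk3 ATAC (from 97.8) and 95.2 for Ntrk3 H3K27ac (from 97.8).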

Other observations

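All tests in this part were chosen after the results were seen. Within the Hox clusters, acetylation followed the position of the genes. Of 27 genes of paralog groups 1 to 9, 26 had H3K27ac within 1 kb of an end, against 3 of 12 genes of groups 10 to 13 (two-sided Fisher's exact test, p = 9.45e-06; neighbouring genes share wide peaks and are not independent). ATAC peaks were at 18 of 27 and 5 of 12 of these genes (Fisher p = 0.174). On the X chromosome, 44.0% of 966 protein-coding genes were open at an end, against 61.9% of 20661 autosomal genes (Fisher p = 4.81e-28). The acetylated shares were 32.4% and 50.6% (Fisher p = 5.65e-29). Depth is unknown and the cause of these differences was not tested, so they are differences in called peaks only.

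Around Runx3, 46 ATAC peaks lay within 200 kb, where the median such window holds 2 and the 99th percentile is 17. A tandem repeat with a unit of 1 to 5 kb is argued against. At the best such unit, 23.1% of the spacings between neighbouring peaks were whole multiples (1 to 4), and random placement gave 24.3% on average. Shorter and longer units were not searched, so repeats of such units are not excluded. Extra copies of the region from the BAC transgene cannot be told apart from an active region: 25% of 52 distal peaks were acetylated (95% interval 15.2 to 38.2), between the tenth percentile (7.10%) and the median (26.7%) of 100 other dense windows, and the extent of the BAC is not known. On an active regulatory region the acetylated share does not decide. Its interval includes the 33.9% that distal peaks of the same widths predict (the 200 closest in width for each peak). A region of ordinary active elements could also have such a share. The 9 H3K27ac peaks between Syf2 and Clic4 ranked 270 among 21883 genes, a rank that carries no test. Input DNA, which would show the copies, was not analysed here.

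Between Hrh1 and Atg7 (chromosome 6, 114483299 to 114643126), 46 narrow ATAC peaks (median 141 bp) stood at even distances. Of 45 spacings, 44 (97.8%) were whole multiples of 2400 bp within 10%, against 24.8% on average and at most 37.8% under random placement (permutation p = 0.001, the smallest that 1000 placements can give); the highest share among blocks of 20 peaks elsewhere was 78.9%. A tandem repeat in the reference is a candidate explanation, as a hypothesis; a repeat annotation was not used here. Whether the peaks are active regulatory elements is left open by their acetylation, which does not bear on the spacing. Of the 46 peaks, 1 was acetylated (exact 95% interval up to 11.53%), where their widths predict 12.3%. However, 8 of 100 other dense windows had as low an acetylated share for their widths.

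Glial and neural crest genes were acetylated in 11 of 22 cases, and 4 of the 22 also stand in other lists (Egr2, Foxd3, Gfra3 and Ngfr). Other cells of the region admitted alike by the sort are argued against, since the pooled spinal, mesenchymal and vascular lists, without shared genes, were acetylated in 7.89% of 76 genes (6 genes; 0% to 15.8% in each list). Because the glial list was singled out as the highest, acetylation was shuffled over the genes of these 5 lists, taking the list furthest above the others each time (permutation p = 0.00045). Of 8 core glial genes, picked after their values were seen, 6 were acetylated. Glial or neural crest cells that passed the GFP sort therefore cannot be told apart from acetylation of these genes in the neurons themselves, because positions carry no level and a share of cells cannot be read from them.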
